A study of Homo sapiens with 8 samples.

How the data were processed

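The series holds 8 samples of total RNA from HaCaT keratinocytes, each hybridised to 1 Affymetrix human transcriptome array. Per the labels' protocols, cells were treated with 0.3% DMSO or 30 μM apratyramide for 3 h or 12 h, RNA was isolated with a column kit, and biotinylated targets were prepared from 250 ng of total RNA. Groups and replicate numbers were taken from the sample titles, which gives 4 groups of 2.

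The deposited table holds log2 values, made by the authors with RMA (background correction, quantile normalisation and summarisation of probes), per the submitters' processing notes, which also name limma and give no version or design. The values fit that unit, with the same maximum of 13.498 on all 8 arrays, as quantile normalisation leaves it. RMA gives every array nearly the same distribution, so a change shared by most transcripts would not be seen. No scanner files and no detection calls were used here, so a dim gene cannot be told from background by a test, and changes of dim genes are understated. All 8 columns of the table were matched to samples by name, and no genome build is given in the sources used here, so no coordinates are reported.

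Of 65528 rows, 1555 are not transcript clusters (control and exon-level rows). The platform annotation pairs 22178 probe sets with 1 gene symbol and 1354 with several, and 41996 rows have no symbol in it. Symbols were updated through the Entrez identifier or a synonym with a table of RefSeq genes, which changed 280, and 4 were kept as given. Only probe sets with 1 symbol were tested, and for the 338 genes with more than 1 such probe set the one with the highest mean signal was used, which gave 21824 genes. No filter on low signal was applied. Genes without such a probe set, PDGFB among them, were not analysed here.

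Differences were tested with limma 3.58.1 in R 4.3.3 by lmFit and eBayes on the log2 values, with a mean per group over all 8 arrays (4 residual degrees of freedom, and 2.88 more from the moderation). The contrasts were apratyramide against DMSO at 3 h and at 12 h, their difference (the interaction) and DMSO at 12 h against DMSO at 3 h. A gene said to rise or fall with apratyramide was higher or lower than in DMSO of the same time, whatever its change over time. Adjusted p values are Benjamini-Hochberg values over all genes, two-sided, with a threshold of 0.05. Errors of differences are limma standard errors from the pooled spread, and errors of signals are SDs of 2 arrays. With 2 arrays a group, no permutation of the samples was used.

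Before the data were examined, 23 gene lists were written from textbook knowledge, with 536 entries of which 463 were measured. They cover stress responses, growth factors, cytokines, interferon and p53 targets, cholesterol synthesis, the cell cycle, ribosome biogenesis, histones, autophagy, keratinocyte biology and markers of fibroblasts, melanocytes, endothelial cells and leukocytes. Some genes are in more than 1 list. Each list was tested with limma's camera at a preset correlation between genes of 0.01, adjusted over the lists of a contrast, and again with an estimated correlation. The preset form takes its degrees of freedom from the number of genes, and the estimated form from the arrays. Very small p values of the preset form therefore do not measure variation between cultures. For aminoacyl-tRNA synthetases at 12 h, camera gave unadjusted p values of 1.75e-09 and 0.00282, although the estimated correlation was -0.0295. The named genes also follow a rule fixed at that time. It takes the 8 highest and 8 lowest fold changes of called genes at each time whose replicates do not overlap (6 for the other contrasts), up to 4 called members of each list by size of change, and VEGFA, PDGFB, FGF2 and HBEGF in any case. Other list members that the text gives as examples (TRIB3, ASNS, PSAT1, PHGDH, PPP1R15A, TGFA, TXNRD1, CDC6 and members at 12 h beyond 4 a list) were chosen after their values were seen.

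The steps were tested on simulated data with 50 genes changed by each of 4 sizes among 21824. The simulated noise was independent between genes, without the direction that replicate arrays share in these data. At 3 h, 78% of changes of 0.5 log2 units and 96% of changes of 1 were recovered, and at 12 h 72% and 94%, with 7 and 6 false calls. These shares depend on the number of genes changed and are not the power of the real comparisons, of which that at 3 h called 12 genes. A list shifted by 0.3 was called and 0 of the others were. As the simulated genes were independent, this does not show how often a list of correlated genes is called falsely. The estimated correlation was 0.2598 for the G2 and M phase list. Alternatives were the replicate number as a block, other normalisations, a filter on dim genes, other rules for probe sets, other estimates of the spread, a fold change threshold, and leaving out each array. A crossed block and the background of G and C rich probe sets as a covariate were added after the data were seen. That background is the mean of 7 background probe sets, with 19 to 25 G or C bases. Figures were drawn with matplotlib 3.10.9.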

Results

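Gene expression was measured in HaCaT cells, an immortalised line of human skin keratinocytes, treated with apratyramide or with its vehicle. Apratyramide is a peptidic compound of marine origin that the submitters' title links to the induction of VEGF-A and further growth factors. The cells received 30 μM apratyramide or 0.3% DMSO and were collected after 3 h or 12 h. The 4 groups held 2 arrays each, described by the submitters as biological duplicates, and the comparisons ask which transcripts the compound changed at each time. Values are log2 microarray signals, the median over all rows of an array lay between 3.82 and 3.83 on the 8 arrays, and 21824 genes were tested. With 2 arrays a group, the number of arrays limits the precision of every value.

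Replicate arrays correlated across genes at 0.9978 in DMSO at 3 h, 0.9976 in apratyramide at 3 h, 0.9935 in DMSO at 12 h and 0.9984 in apratyramide at 12 h. The median SD of a gene between replicates was 0.098 log2 units in DMSO at 12 h, against 0.053, 0.055 and 0.039 in DMSO at 3 h, apratyramide at 3 h and apratyramide at 12 h. DMSO replicate 2 at 12 h correlated at 0.9953 and 0.9958 with the DMSO arrays at 3 h, above its 0.9935 with the other DMSO array at 12 h, which in turn correlated at 0.995 and 0.9954 with the apratyramide arrays at 12 h. At 3 h too, DMSO replicate 1 with apratyramide replicate 2 (0.9981) and DMSO replicate 2 with apratyramide replicate 1 (0.9979) lay above the replicates of either group. The arrays also differed in the signal of background probe sets rich in G and C, which match no transcript. This background was 7.94 and 7.64 in DMSO at 12 h and 7.85 on both apratyramide arrays at 12 h, and lay between 7.57 and 7.68 at 3 h, so it moved partly with time.

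**Figure D1:**
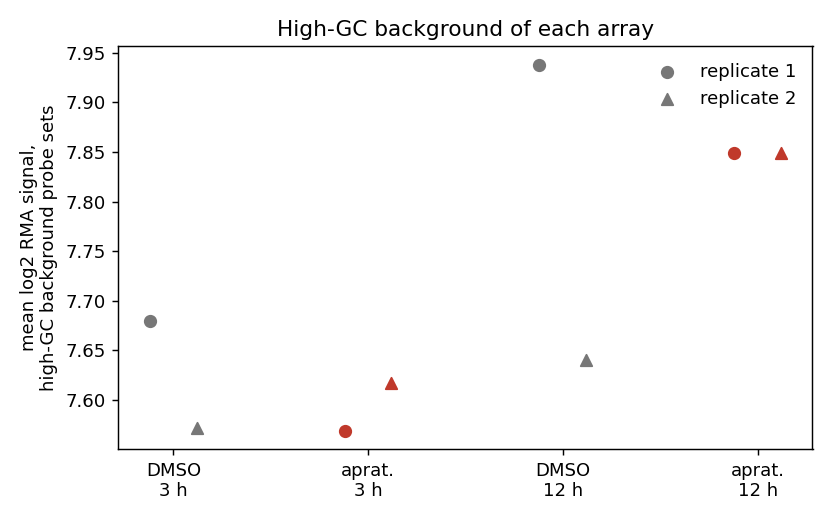
Mean log2 RMA signal of the background probe sets rich in G and C on each array (y axis), by group (x axis), with circles for replicate 1, triangles for replicate 2, grey for DMSO and red for apratyramide. DMSO replicate 2 at 12 h, at 7.64, sits with the 3 h arrays and below the other 12 h arrays, which lie between 7.85 and 7.94.

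After 3 h, apratyramide raised a small set of genes of the endoplasmic reticulum stress response, the integrated stress response and cholesterol synthesis. The highest fold change was that of HERPUD1, which takes part in degrading misfolded proteins of the endoplasmic reticulum and rose by 1.93 ± 0.08 log2 units (SE, n = 2 per group), or 3.8-fold, with a limma adjusted p of 0.00145. CHAC1, a glutathione-degrading enzyme, rose 2.7-fold, and DDIT3 and DDIT4, a stress transcription factor and an inhibitor of mTORC1, rose 2.48-fold and 2.44-fold. INSIG1, which retains the sterol sensor SCAP in the endoplasmic reticulum, rose 2.57-fold and HMGCS1, an early enzyme of the mevalonate pathway, rose 2.29-fold. GRHL3, a transcription factor of epidermal differentiation, fell by 0.53 ± 0.05 log2 units and was the only gene called lower.

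In all, 12 of 21824 genes passed an adjusted p of 0.05 in limma at 3 h, 11 higher and 1 lower, and 6 of them rose at least 2-fold. The other calls were MSMO1 (0.91 log2 units) and SQLE (0.61), both enzymes of sterol synthesis, the chaperone HSPA5 (0.71), its co-chaperone DNAJB9 (0.69), and the transcription factor CREB3L2 (0.49), which falls outside the naming rule and is named after its value was seen. The count rests on each array of that time. Without any 1 of the 4 arrays at 3 h, 1 or 2 genes passed, without either apratyramide array at 12 h 5 and without either DMSO array at 12 h 20, and HERPUD1 alone among the named genes passed in all 19 alternatives in which it was tested. DDIT3 passed in 8 of 18, HSPA5 in 10 of 19, and MSMO1, SQLE, DNAJB9 and GRHL3 in 9 of 19 each.

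Of the gene lists fixed beforehand, 5 lay higher and 4 lower at 3 h in limma's camera test, which compares a list with all other genes. With an estimated correlation 4 of these 9 lists passed, 4 higher and 0 lower. Among 30 measured targets of the integrated stress response factor ATF4, 3 rose over all genes tested and 15 when adjusted over the list alone, with a median of 0.20 and an adjusted p of 1.72e-23. Among 25 chaperones and quality control genes of the endoplasmic reticulum, targets of ATF6 and XBP1, 3 rose over all genes and 17 when adjusted over the list alone (median 0.23, adjusted p 2.19e-37). Of 18 genes of cholesterol synthesis, 4 rose over all genes and 11 when adjusted over the list alone (median 0.24, adjusted p 1.77e-26). Of 19 cytosolic aminoacyl-tRNA synthetases, which charge tRNAs with amino acids, 0 passed over all genes and 1 was higher when adjusted over the list alone, with 15 above 0 and a median of 0.084 (adjusted p 1.56e-06). These 4 lists also passed with an estimated correlation, at adjusted p values of 0.029, 0.0158, 0.00919 and 0.029.

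The heat shock list was also higher at 3 h, with 13 of 14 members above 0, a median of 0.088 and an adjusted p of 2.92e-06, but not with an estimated correlation (adjusted p = 0.052). Lower lists were S phase and DNA replication (median -0.078, adjusted p 5.79e-05), G2 and M phase (-0.04, 0.0132), ribosome biogenesis (-0.063, 0.00435) and keratinocyte differentiation (-0.043, 0.0322). With an estimated correlation these lists had adjusted p values of 0.14, 0.504, 0.0952 and 0.504, so none of them passed. Of these 5 lists only keratinocyte differentiation held a member called over all genes, GRHL3. The call of that list ended without DMSO replicate 1 (median -0.046, adjusted p 0.188), apratyramide replicate 1 (-0.051, 0.0724) or apratyramide replicate 2 at 3 h (-0.058, 0.107), where the median was no smaller in size, and with the background rich in G and C as a covariate (-0.016, 0.191), where it was smaller. Without DMSO replicate 2 or apratyramide replicate 2 at 3 h the calls also ended for G2 and M phase, whose median shrank to -0.014 and -0.009 (adjusted p 0.319 and 0.311), and for ribosome biogenesis, whose median was -0.05 and -0.07 (adjusted p 0.0501 and 0.0541).

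VEGFA, the vascular endothelial growth factor of the series title, had a log2 signal of 7.13 ± 0.06 (SD, n = 2) in DMSO and 7.79 ± 0.02 in apratyramide at 3 h. Its difference of 0.66 ± 0.07 log2 units (SE) had an adjusted p of 0.0562 in limma and did not pass. Both apratyramide arrays lay above both DMSO arrays, but the groups were apart in either direction for 31.8% of all genes at 3 h, where chance gives 33.3%. HBEGF, a ligand of the EGF receptor, differed by 0.73 ± 0.13 (adjusted p 0.311) and FGF2 by -0.14 ± 0.08 (adjusted p 1). None of the 36 measured secreted growth factors passed over all genes, 2 were higher and 1 lower when adjusted over the list alone, and the list did not pass (adjusted p 0.863). Its median was -0.015, its mean 0.023. PDGFB, named in advance beside these, was not analysed here.

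**Figure D2:**
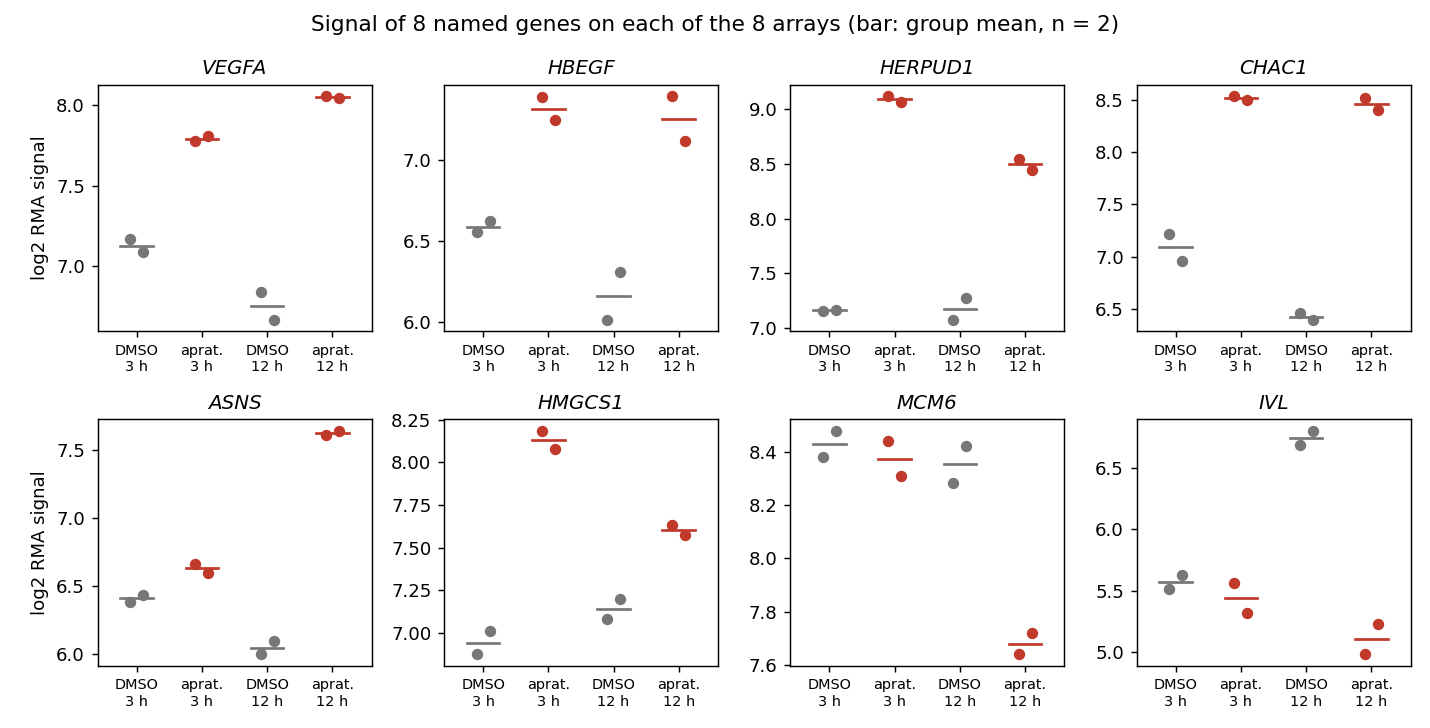
Log2 RMA signal (y axis) of VEGFA, HBEGF, HERPUD1, CHAC1, ASNS, HMGCS1, MCM6 and IVL on each of the 8 arrays, by group (x axis), with points for arrays and bars for means of 2 arrays, grey for DMSO and red for apratyramide. VEGFA had means of 7.13 and 7.79 at 3 h and of 6.75 and 8.05 at 12 h, and the y axes do not start at 0.

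After 12 h more genes were called than at 3 h, and growth factor genes were among them. VEGFA reached 8.05 ± 0.01 (SD, n = 2) against 6.75 ± 0.12 in DMSO, a rise of 1.29 ± 0.07 log2 units (SE) or 2.45-fold (limma adjusted p 0.000632), and passed in all 19 alternatives. HBEGF rose by 1.09 ± 0.13, or 2.14-fold (adjusted p 0.00648). The other called growth factors were EREG (0.95) and TGFA (0.44), which are ligands of the EGF receptor, and NRG1 (0.68), a ligand of ERBB3 and ERBB4. NRG1 has 3 probe sets and their mean differed by 0.17 with an adjusted p of 0.393. Part of the differences of VEGFA, HBEGF, EREG and NRG1 lies in DMSO. There the mean signal fell from 3 h to 12 h for VEGFA (7.13 to 6.75), HBEGF (6.59 to 6.16), EREG (4.83 to 4.28) and NRG1 (7.81 to 6.95). With apratyramide VEGFA went from 7.79 to 8.05 and EREG from 5.21 to 5.23. HBEGF went from 7.31 to 7.25 and NRG1 from 8.02 to 7.635 with apratyramide, and these changes over time were not tested. FGF2 differed by 0.08 ± 0.08 (adjusted p 0.701). Of the 36 growth factors, 5 rose over all genes and 7 when adjusted over the list alone, with a median of 0.07. The list passed in camera (adjusted p 0.000197), but not with an estimated correlation (adjusted p = 0.156).

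At 12 h, 1041 of 21824 genes passed in limma, 568 higher and 473 lower, and 41 rose and 14 fell at least 2-fold. Both treated arrays lay above both DMSO arrays, or both lay below them, for 42.8% of genes, where chance gives 33.3%. At 3 h the share was 31.8%. The count and its balance depend on single arrays. Without apratyramide replicate 1 or 2 at 12 h it was 122 (92 higher and 30 lower) or 157 (116 and 41), and without DMSO replicate 1 or 2 at 12 h 2703 (1217 and 1486) or 852 (570 and 282). It was 462 without either DMSO array at 3 h and 524 without either apratyramide array at 3 h, which enter through the shared spread.

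The highest fold changes at 12 h were those of IL1A, an alarmin cytokine of keratinocytes, and TXNIP, an inhibitor of thioredoxin and of glucose uptake. IL1A rose by 2.56 ± 0.21 log2 units (SE, n = 2 per group), or 5.88-fold, with a limma adjusted p of 0.0021, and TXNIP by 2.55 ± 0.09, or 5.85-fold, with 0.000397. Part of both differences lies in DMSO, where IL1A fell from 5.76 at 3 h to 4.465 ± 0.47 (SD) at 12 h and TXNIP from 6.73 to 5.76. With apratyramide IL1A went from 6.57 to 7.02 and TXNIP from 7.50 to 8.31. WIPI1, which acts in autophagosome formation, rose 4.28-fold, CHAC1 4.11-fold, ULBP1, a ligand of the NKG2D receptor of natural killer cells, 3.96-fold, and the cystine transporter subunit SLC7A11 3.32-fold. The lowest were IVL (involucrin, of the cornified envelope), which was 3.13-fold lower, OLFM4 (2.94-fold lower), TNFSF10, which encodes the death ligand TRAIL (2.83-fold lower), and FAM111B (2.74-fold lower). The glutamate transporter SLC1A3 (-1.38 log2 units), the protease TMPRSS11E (-1.22), the ubiquitin ligase RNF152 (-1.14) and the chemokine CCL2 (-1.12) were also lower. With apratyramide, CCL2 (6.79 to 7.79) and TNFSF10 (4.50 to 5.28) rose from 3 h to 12 h, but less than in DMSO (7.01 to 8.91 and 4.935 to 6.785). RNF152 stayed at 6.82 with apratyramide and rose in DMSO (7.30 to 7.96). With apratyramide the mean signals of IVL, OLFM4, FAM111B, SLC1A3 and TMPRSS11E were lower at 12 h than at 3 h. Changes over time with apratyramide were not tested. TMPRSS11E passed in 13 of its 18 alternatives, and the other genes named here passed in every alternative that tested them.

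Lists of ATF4 targets, endoplasmic reticulum chaperones, aminoacyl-tRNA synthetases and cholesterol synthesis were higher at 12 h. Of the 30 ATF4 targets, 21 rose over all genes and 24 when adjusted over the list alone, with a median of 0.64 and a camera adjusted p of 2.65e-30. They included TRIB3 (1.59 log2 units) and ASNS, or asparagine synthetase (1.58), the serine synthesis enzymes PSAT1 (1.02) and PHGDH (0.68), and PPP1R15A (1.01), which directs dephosphorylation of eIF2α. Of the 25 endoplasmic reticulum chaperones and quality control genes, 19 rose over all genes and 23 when adjusted over the list alone (median 0.53, adjusted p 2.88e-27), among them SEC24D of the COPII coat (1.42), HERPUD1 (1.32), the chaperone HYOU1 (1.05) and the stress sensor ERN1 (0.996). Of the 19 aminoacyl-tRNA synthetases, 9 rose over all genes and 12 when adjusted over the list alone (median 0.25, adjusted p 5.76e-09), led by WARS1 (1.17), SARS1 (1.09) and AARS1 (0.94). Of the 18 cholesterol genes, 8 rose over all genes and 13 when adjusted over the list alone (median 0.32, adjusted p 3e-11), with INSIG1 at 1.14, CYP51A1 at 0.89 and DHCR7 at 0.79. With an estimated correlation each of these 4 lists had an adjusted p of 0.0162.

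Genes of the cell cycle were lower at 12 h. Of 27 genes of S phase and DNA replication, 17 fell and 1 rose over all genes, and 21 fell and 1 rose when adjusted over the list alone (median -0.42, adjusted p 9.96e-19, and 0.0164 with an estimated correlation). MCM10 (-0.74), the helicase subunit MCM6 (-0.67), CLSPN (-0.63) and PCNA, the sliding clamp of DNA polymerase (-0.59), fell, while the licensing factor CDC6 rose by 0.38. Of 27 genes of G2 and M phase, 10 fell over all genes and 20 when adjusted over the list alone, including CDK1 (-0.57), ASPM (-0.49) and KIF20A (-0.43), with a median of -0.28. CDK1 passed in 8 of 19 alternatives (adjusted p up to 0.224). The G2 and M phase list passed in camera (adjusted p 3.54e-14), but not with an estimated correlation (adjusted p = 0.0927). Of 20 ribosome biogenesis genes, 1 fell over all genes, UTP20 (-0.63), and 2 when adjusted over the list alone (median -0.098, adjusted p 0.000255, and 0.0444 with an estimated correlation).

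The heat shock list was lower at 12 h. Of its 14 members 5 fell over all genes and 10 when adjusted over the list alone (median -0.25, adjusted p 1.34e-09, and 0.0192 with an estimated correlation). HSPA4L (-1.05), CHORDC1 (-0.78), DNAJA1 (-0.69) and HSPH1 (-0.60), all cytosolic chaperones or co-chaperones, fell. CHORDC1 passed in 13 of 19 alternatives and DNAJA1 in all 19.

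Immediate early genes were higher at 12 h, with 9 of 24 called over all genes and 12 higher and 1 lower when adjusted over the list alone (median 0.30). JUND rose by 0.86, ATF3 by 0.70, MYC by 0.69 and KLF6 by 0.64. The list passed in camera (adjusted p 2.36e-07), but not with an estimated correlation (adjusted p = 0.129). The NRF2 list was higher too (median 0.14, adjusted p 0.00505), with 4 of 17 members higher and 1 lower over all genes and 5 higher and 1 lower when adjusted over the list alone. It did not pass with an estimated correlation (adjusted p = 0.0927) or without DMSO replicate 1 at 12 h (0.0505, with a median of 0.19). Its called members were SLC7A11, which is also in the ATF4 list, the ferritin light chain FTL (0.43), PGD of the pentose phosphate pathway (0.35), the thioredoxin reductase TXNRD1 (0.35) and, lower, the reductase AKR1B10 (-0.83). PGD passed in 8 of 19 alternatives. Interferon-stimulated genes were lower (median -0.037, adjusted p 0.023), with OAS3 (-0.37), OAS1 (-0.36) and IFIT1 (-0.35) as the 3 of 20 that fell over all genes and when adjusted over the list alone. That list did not pass with an estimated correlation (adjusted p = 0.119), and its call also ended without DMSO replicate 2 (median -0.07, adjusted p 0.0541) or apratyramide replicate 2 at 12 h (-0.011, 0.0742) and over genes above the median signal (0.219). OAS3 passed in 15 of 19 alternatives, OAS1 in 6 of 18 and IFIT1 in 8 of 18.

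Other lists did not pass in camera at 12 h but held members that changed in both directions. In keratinocyte differentiation (adjusted p 0.197), 2 of 26 members rose and 6 fell over all genes, and 4 rose and 6 fell when adjusted over the list alone. IVL, GRHL3 (-0.95), KRT1 (-0.89) and KRT13 (-0.87) were lower than in DMSO at 12 h. From 3 h to 12 h the mean signal of KRT13 rose in DMSO (9.16 to 10.42) and less with apratyramide (9.04 to 9.55). That of IVL rose in DMSO (5.57 to 6.75) and went from 5.44 to 5.10 with apratyramide. With apratyramide the mean signals of GRHL3 and KRT1 were also lower at 12 h than at 3 h, which was not tested. The median of the list was -0.021, and ran from -0.086 to 0.145 over its 15 alternatives. The list passed as lower in 1 of these, the fit without DMSO replicate 2 at 12 h (median -0.073), which leaves 1 DMSO array at that time. Among 19 basal keratinocyte and wound-edge genes (adjusted p 0.555), KRT15 (-0.92) and the collagenase MMP13 (-0.85) were lower than in DMSO at 12 h. PLAU (0.37) and its receptor PLAUR (0.35) were higher, and 3 were higher and 5 lower when adjusted over the list alone. KRT15 rose from 3 h to 12 h in DMSO (5.96 to 7.42) and less with apratyramide (5.90 to 6.50). MMP13 did the same (7.08 to 8.33 in DMSO and 7.34 to 7.48 with apratyramide). PLAU passed in 12 and PLAUR in 8 of 19 alternatives, and KRT1 in 11 of 18. Among 21 cytokines and NF-kB targets (adjusted p 0.555), 4 rose and 4 fell over all genes, and 6 rose and 4 fell when adjusted over the list alone, with IL1A and IL1B (0.85) higher and CCL2 and CXCL1 (-0.75) lower. The mean signal of IL1B fell from 3 h to 12 h in DMSO (7.51 to 6.805) and went from 7.76 to 7.66 with apratyramide. Autophagy and lysosome genes (adjusted p 0.0626) had 5 of 25 higher and 1 lower over all genes, and 6 and 2 when adjusted over the list alone, with WIPI1, GABARAPL1 (0.60) and the cargo receptor SQSTM1 (0.59) higher. Without DMSO replicate 2 or apratyramide replicate 2 at 12 h that list passed as higher (adjusted p 0.00821 and 0.0287), as it did over genes above the median signal (0.0494) and with the background covariate (0.0364). Targets of p53 (adjusted p 0.573) had 3 of 19 higher, led by GADD45A (1.03), and 1 lower, with the same counts when adjusted over the list alone. Targets of HIF1A (adjusted p 0.542) had 3 of 22 higher, led by NDRG1 (0.59), and 2 lower, or 6 and 3 when adjusted over the list alone.

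Histone genes (adjusted p 0.338) and markers of other cell types did not pass at 12 h either. The marker lists of dermal fibroblasts, melanocytes, endothelial cells and leukocytes had adjusted p values of 0.555, 0.338, 0.555 and 0.279, and at 3 h of 0.179, 0.912, 0.912 and 0.548. Of their members CD68, a lysosomal protein that serves as a macrophage marker, was the only one called at 12 h (0.41). Medians and means had opposite signs at 12 h for targets of HIF1A (-0.008 and 0.054), targets of p53 (-0.041 and 0.075) and basal keratinocyte genes (0.012 and -0.082).

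**Figure D3:**
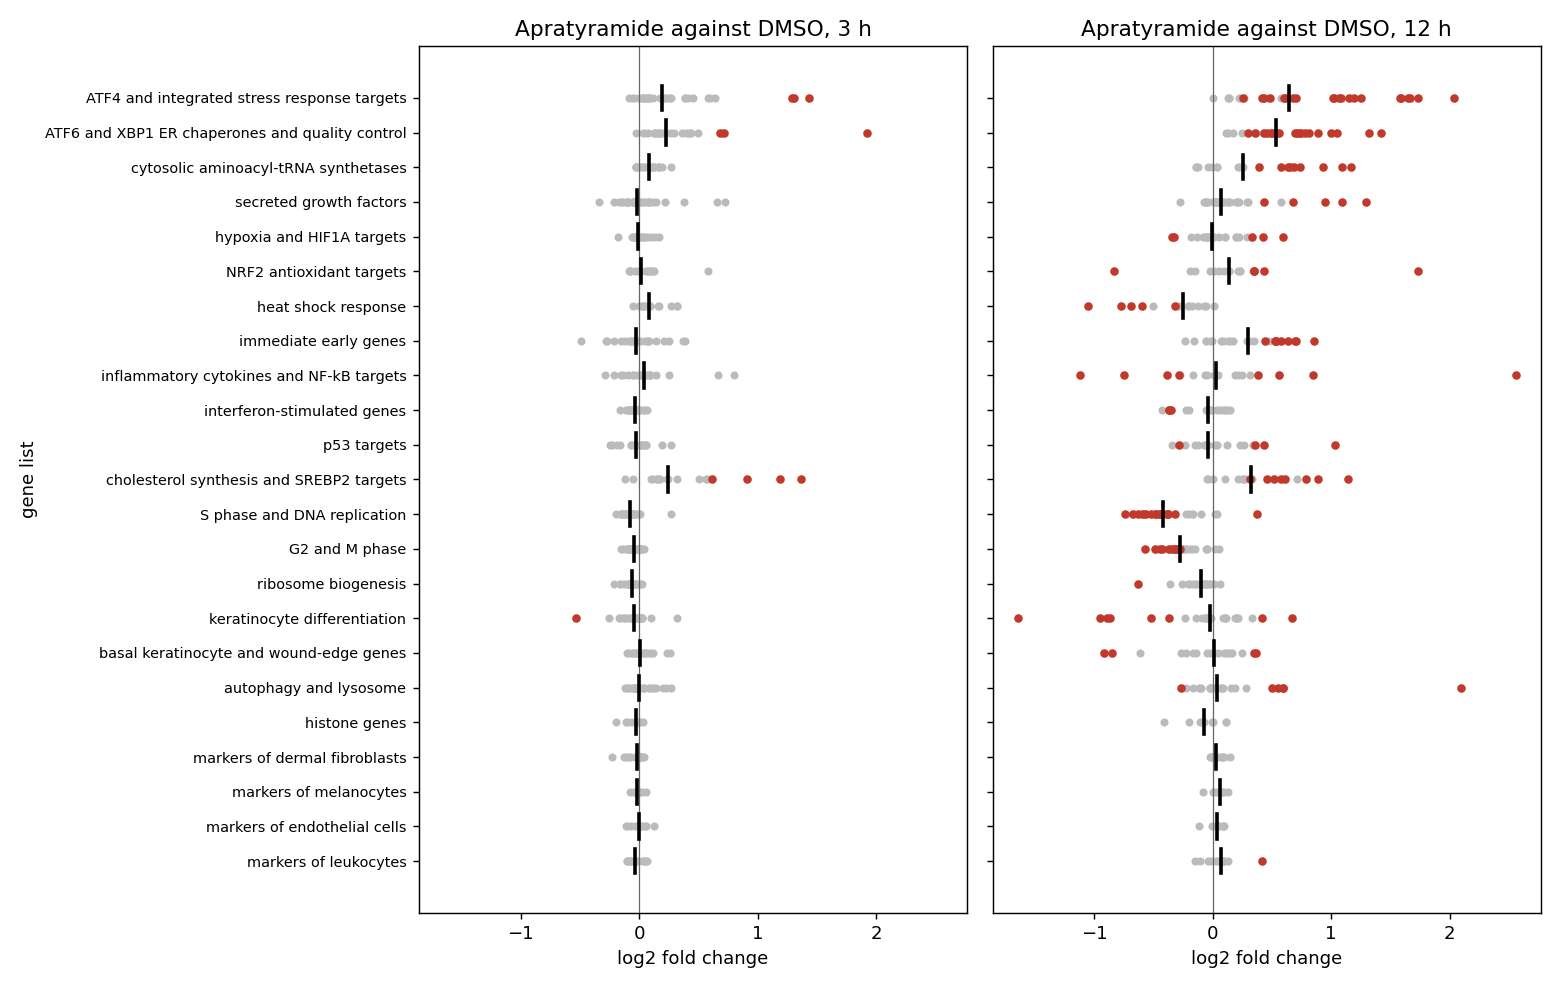
Log2 fold change of apratyramide against DMSO (x axis) at 3 h and at 12 h for the measured members of each gene list (y axis), with a point per gene, red where the limma adjusted p over all genes was below 0.05, and a black bar at the median of the list. The median of the ATF4 targets lay at 0.20 at 3 h and 0.64 at 12 h, and that of S phase genes at -0.078 and -0.42.

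The 12 genes called at 3 h were all called at 12 h in the same direction, where independent lists of these sizes would share 0.286 higher and 0.022 lower genes. Conversely, 874 of the 1041 genes called at 12 h (84%) had the same sign at 3 h, against 58.2% of all genes. Across genes the fold changes at both times correlated at 0.335, and genes are not independent replicates. The comparisons at 3 h and at 12 h share no arrays, only the estimate of the spread.

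The change of the effect from 3 h to 12 h was tested as an interaction, in which 37 genes passed in limma, 25 with a higher and 12 with a lower effect at 12 h. The effect was higher at 12 h by 1.89 ± 0.16 log2 units (SE) for WIPI1, 1.78 for TXNIP, 1.36 for ASNS, 1.33 for the xenobiotic-metabolising enzyme CYP1A1, 1.17 for LCN2, an iron-binding defence protein, and 1.0 for WARS1. It was lower by -1.51 ± 0.16 for IVL, -1.47 for OLFM4, -1.16 for SLC1A3, -1.08 for the chaperone HSPA2, -0.90 for the taurine transporter SLC6A6 and -0.87 for HSPH1. IVL passed in 8 of 18 alternatives, OLFM4 in 9 of 17 and the other 10 genes named here in 10 of 18. VEGFA did not pass (0.63, adjusted p 0.0798), and neither did HBEGF (0.37, 0.621), so a difference between the times was not shown for them. The count was 0 in limma without any 1 of the arrays of the other groups than DMSO at 12 h (1313 to 1637 genes at an unadjusted p below 0.05) and 140 without DMSO replicate 1 at 12 h.

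Among the lists, ATF4 targets (median 0.46), aminoacyl-tRNA synthetases (0.18), heat shock genes (-0.39) and S phase genes (-0.34) changed their effect with adjusted p values in camera of 1.02e-23, 9.75e-09, 1.15e-15 and 3.07e-17, and each had 0.0235 with an estimated correlation. Chaperones of the endoplasmic reticulum (0.22), growth factors (0.10), NRF2 targets (0.17), immediate early genes (0.23) and G2 and M phase genes (-0.25) passed in camera, at adjusted p values of 7.3e-10, 4.53e-05, 0.0287, 1.85e-09 and 1.56e-11. With an estimated correlation these had adjusted p values of 0.0814, 0.165, 0.165, 0.154 and 0.157. For cholesterol genes no change was detected (median 0.023, adjusted p 0.975).

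The vehicle cultures changed between the times as well. From 3 h to 12 h in DMSO, 536 genes passed in limma, 261 higher and 275 lower. CCL2 rose by 1.90 ± 0.10 log2 units (SE, n = 2 per group), TNFSF10 by 1.85, TNFAIP2 by 1.84, the ubiquitin ligase TRIM31 by 1.62, ID1, an inhibitor of helix-loop-helix transcription factors, by 1.59, and the basal keratin KRT15 by 1.46. Follistatin, the activin antagonist encoded by FST, fell by 2.06 ± 0.05. SYT14 (-1.57), NAV3 (-1.48), the ectonucleotidase NT5E (-1.38), SPRR1B of the cornified envelope (-1.35) and IL1A (-1.30) fell too. IL1A passed in this comparison in 9 of 19 alternatives (adjusted p 0.00417 to 0.225), SYT14 and TRIM31 in 15 of 18 each, and SPRR1B in 16 of 19. The 6 genes named here as higher were all called lower with apratyramide at 12 h, CCL2, TNFSF10 and KRT15 as given above, TNFAIP2 by -0.39 (adjusted p 0.0107), TRIM31 by -0.84 (0.036) and ID1 by -0.33 (0.0238). Of the 6 named as lower, IL1A was called higher with apratyramide and the other 5 were not called. The DMSO arrays of 12 h enter these comparisons with opposite signs, which alone favours opposite directions, and no value expected from this was computed. The count was 1891 without DMSO replicate 2 at 12 h and 72 or 49 without DMSO replicate 1 or 2 at 3 h. It was 229 without either apratyramide array at 3 h and 184 without either at 12 h, which enter through the shared spread.

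Ribosome biogenesis genes were lower in DMSO at 12 h than at 3 h, with 7 of 20 called over all genes and 18 when adjusted over the list alone (median -0.37, adjusted p 1.87e-17, and 0.0147 with an estimated correlation). Another 9 lists passed in camera, and none of these with an estimated correlation. Cholesterol genes (adjusted p = 0.183 with an estimated correlation) and G2 and M phase genes (0.361) were higher. Aminoacyl-tRNA synthetases (0.0986 with an estimated correlation) were lower, as were ATF4 targets, endoplasmic reticulum chaperones, growth factors, immediate early genes, S phase genes and histone genes (each adjusted p = 0.361). Without DMSO replicate 2 at 12 h, 4 lists passed in place of 10.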

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

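Of the tests in this part, that of the background as the cause of the spread between replicates, and that of culture stages, were chosen only after the result was seen, as was the fit with the background as a covariate.

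The difference between the apratyramide effects at 12 h and 3 h, tested as an interaction in limma, passed for 37 genes. The named ones with a higher effect at 12 h were WIPI1 (1.89 log2 units), TXNIP (1.78), ASNS (1.36), CYP1A1 (1.33), LCN2 (1.17), WARS1 (1.0), ERN1 (0.94), SARS1 (0.93), HYOU1 (0.68) and AARS1 (0.67). Those with a lower effect were IVL (-1.51), OLFM4 (-1.47), SLC1A3 (-1.16), HSPA2 (-1.08), SLC6A6 (-0.90), HSPH1 (-0.87), DNAJA1 (-0.86), KRT15 (-0.86) and KRT13 (-0.75). HSPH1 and DNAJA1 had values above 0 at 3 h (0.27 and 0.17, not called) and fell at 12 h.

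The same test passed for 9 lists in camera, 4 of which also passed with an estimated correlation. These 4 were ATF4 targets, whose median change of the effect was 0.46, aminoacyl-tRNA synthetases (0.18), heat shock genes (-0.39) and S phase genes (-0.34). The other 5 did not pass with an estimated correlation, endoplasmic reticulum chaperones (median 0.22, adjusted p = 0.0814 with an estimated correlation), growth factors (0.10, adjusted p = 0.165), NRF2 targets (0.17, adjusted p = 0.165), immediate early genes (0.23, adjusted p = 0.154) and G2 and M phase genes (-0.25, adjusted p = 0.157). The array background rich in G and C was higher on most 12 h arrays, so it was weighed as a technical source for the ATF4 list, whose median changed most of the 9. With the background as a covariate the median for ATF4 targets was 0.433, against 0.459 without it. A background shift over time that DMSO and apratyramide share cancels in the interaction. The fit therefore tests only the rest of the background, and is a weak test of it. Over the 8 fits that left out an array the median ran from 0.405 to 0.502, so no 1 array accounts for it. With the background covariate 10 lists passed, the 9 among them. A longer exposure to the compound remains as a hypothesis, found and tested on the same data.

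Replicates of DMSO at 3 h, apratyramide at 3 h and DMSO at 12 h differed along a shared direction. The differences of same-numbered arrays across genes correlated at -0.384 between the groups at 3 h, 0.485 between the DMSO groups and -0.569 between apratyramide at 3 h and DMSO at 12 h. The background rich in G and C has matching signs, with replicate 2 minus replicate 1 at -0.107, 0.048 and -0.298 in these groups, and as a covariate it lowered the median residual SD from 0.0823 to 0.0523, which 0 of 100 random covariates did, so an array or labelling effect may be the source. For DMSO replicate 2 at 12 h, a wrong label for a 3 h culture is argued against, since on 121 genes it lay at a median of 0.601 (bootstrap interval 0.538 to 0.717) of the way from the DMSO mean at 3 h to the other 12 h array. Different stages of the apratyramide cultures at 3 h cannot be told apart from this, because the slope of their difference on the DMSO time effect was -0.194 over all genes, -0.077 over the 1000 genes with the largest time effect and -0.004 over the 200 largest. These 3 gene sets were set after slopes on these and other sets of genes, some adjusted for the background, had been seen to depend on the set. The time effect itself includes the background difference, and no other biological explanation was tested.

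Some rows outside the main measurement also passed. When every probe set was tested, 203 of 40441 transcript clusters with no gene symbol passed at 12 h, 93 higher and 110 lower, and 1 passed at 3 h. At 12 h this was a smaller share than that of all rows, of which 568 of 65528 passed. Of 1555 control and exon-level rows 21 passed at 12 h, a larger share than that of all rows, and none of them was a background probe set.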

How the results depend on the processing

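The crossed block and the background covariate were chosen after seeing the data. Every named gene, and every list called at 3 h or 12 h, kept its direction in all alternatives run for it, and quantile normalisation, centring on the median and the mean of probe sets left all counts within 1.5 times. Counts are given for 3 h, 12 h, the interaction and DMSO over time, against 12, 1041, 37 and 536. Leaving out an array gave 1 to 20, 122 to 2703, 0 to 140 and 49 to 1891 genes, and a lone array is then assumed to vary like the other groups. At 12 h the lowest count was that without apratyramide replicate 1 and the highest that without DMSO replicate 1. Genes above the median signal gave 22, 1552, 180 and 984, where fewer genes share the adjustment and limma's prior is refitted. Every probe set gave 6, 568, 0 and 213 (for the interaction 4648 rows at an unadjusted p below 0.05), where more rows share it. A trended and robust prior gave 24, 1386, 224 and 871, array weights 29, 495, 26 and 177, and the background covariate 34, 2655, 372 and 1263, where the covariate lowers the residual SD. Only the 4 arrays of a contrast gave 2, 100 and 6 genes for 3 h, 12 h and DMSO over time, with fewer samples. A fold change of at least 2 gave 6, 55, 10 and 32. For array weights and the trended prior the cause was not tested.

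With the replicate number as a block, 5, 535, 0 and 232 genes passed (1734 for the interaction at an unadjusted p below 0.05), and no list lost or gained its call. Differences of same-numbered replicates correlated between -0.569 and 0.485, so no replicate shift common to all groups was seen. These correlations may come from the array background, so they cannot show whether same-numbered cultures were handled together. What the lower counts with the block mean therefore stays open. As the correlation at 3 h was -0.384, a crossed pairing was tried and gave 6, 1313, 31 and 780 genes. For lists, an estimated correlation left 4 of 9, 7 of 12, 4 of 9 and 1 of 10. Leaving out an array gave 6 to 10, 11 to 13, 8 to 10 and 4 to 10 lists. VEGFA at 12 h ran from 1.21 to 1.38 log2 units over 19 alternatives and passed in each, and at 3 h from 0.62 to 0.70, passing in 6 of 19 (adjusted p 0.0119 to 0.684). HBEGF at 12 h passed in 17 of 19. No detection call is used, so signal over background limits dim genes such as IFIT1.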

Other observations

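The tests of both full lists in this part were set before their percentiles were computed, on lists that leave out the genes that prompted them. SLC7A5, NQO1 and KLF10 are also members of lists whose results at 12 h were then known. The percentiles without SLC7A5 and without FASN were added after those of the full lists were known. The prompting genes, and the lists, were chosen after the 12 h results were seen. The random lists were drawn gene by gene, so the percentiles take genes as independent and do not measure variation between cultures.

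CYP1A1 and CYP1B1, enzymes of xenobiotic metabolism outside the lists of the report, were chosen for follow-up after their values at 12 h were seen. CYP1A1 rose by 1.63 log2 units (limma adjusted p 0.000662) and CYP1B1 by 0.99 ± 0.07 (SE, n = 2 per group, adjusted p 0.000954), with interactions of 1.33 and 0.89 (adjusted p 0.0363 and 0.0369), and neither passed at 3 h (0.30 and 0.099). Both are textbook targets of the aryl hydrocarbon receptor. The hypothesis that other targets of this receptor rose as a group was tested on 9 genes. All 9 had values above 0 at 12 h with a median of 0.154, at percentile 98.9 of 10000 random lists matched on mean signal. TIPARP (0.23), SLC7A5 (0.26) and NFE2L2 (0.24) passed, while ALDH3A1 (0.018) and NQO1 (0.054) did not. SLC7A5 is also an ATF4 target, and without it the median was 0.113, at percentile 95.8, so the result suggests a small shared shift at most and does not show that the receptor was active.

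TXNIP, among the highest genes at 12 h, is a target of the glucose-responsive factors MondoA and ChREBP. Of 9 other targets, 7 had values above 0 at 12 h, with a median of 0.19 at percentile 99.7 of random lists. Of these, 2 passed, ARRDC4 (1.21, adjusted p 0.0197), an arrestin related to TXNIP, and FASN (0.46), also a target of SREBP factors. Without FASN the median was 0.184, again at percentile 99.7. KLF10 (-0.23) and ACACA (-0.007) went the other way or stayed near 0. This is consistent with a rise of part of these targets, and ARRDC4 and TXNIP, related in function, could also respond to another signal that the design does not separate.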
